A study of Pimephales promelas with 27 samples.

How the data were processed

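Total RNA of newly hatched fathead minnow, a small freshwater fish used in toxicity testing, was measured on 27 one-colour Agilent arrays with Cy3 label, per the labels. The embryos had been exposed to 1 of 3 sources of naphthenic acids, which are carboxylic acids of crude oil: fresh or aged oil sands process water, the water left after bitumen is extracted from oil sand, or pure naphthenic acids. Each source had its own salt control and 2 doses, with 3 arrays in each of the 9 groups. The doses were 5 and 10 ppm for fresh, 10 and 20 ppm for aged and 1.25 and 2.5 ppm for pure. The labels do not say what the ppm of the process waters count, nor whether the 3 samples of a group came from separate tanks or spawns, so p-values measure the spread between these samples, which may be partly technical.

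The scanner output of each array held a processed signal per spot, an intensity on a linear scale made with Agilent Feature Extraction 10.7.1.1, per the file headers. The headers used here do not state its background steps, and its 75th percentile differed between arrays, from 582 to 2044, so it had not been scaled between them. The same files held median and local background intensities, also deposited as scanned, and flags of 0 or 1 for spots well above background, saturated or not uniform, per the file headers. The value table of the series held the authors' log2 values of the same arrays. Set against the scanner files, its columns had a floor at 3.5, had nearly the same quantiles, as after quantile normalization, and had medians between 7.36 and 7.43. They rose with the scanner signal and were not centred by probe, while the authors' software and background step are not given in the sources used here.

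Of 15744 spots on each array, 536 were control spots and were left out, and the other 15208 were probes spotted once each. A probe was tested if it was well above background on at least 3 of the 27 arrays, which kept 14738 probes. Of these, 10108 were well above background on every array. Between 10930 and 14981 probes were well above background on 1 array, and no probe spot was saturated. The log2 processed signal minus the 75th percentile of its array was fitted with a mean per group over all 27 arrays in limma 3.58.1 (R 4.3.3), with 18 residual degrees of freedom. Contrasts were tested with limma's moderated statistic, and a probe was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested probes. Each dose was compared with the salt control of its own source. The mean of both doses against the control, the step between doses, the fresh effect minus the aged effect at 10 ppm and the difference among the 3 salt controls were also tested.

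No gene was named. The files pair probes with contig names (11862 probes), sequence numbers (3309 probes) or other names (37 probes) and not with genes, and 0 probe names and 0 of the files' systematic names matched the 64593 genes of the reference table (assembly fPimPro1.hap1.1). The gene lists, tissue markers and named-gene rule fixed before the data were examined could therefore not be applied, and none of those lists was tested. In their place, 4 probes are given by identifier: the 2 with the largest rise and the 2 with the largest fall past the threshold at pure 2.5 ppm, a choice made after their values were seen. The probes that rose at pure 2.5 ppm were also tested as a set in the fresh and aged comparisons, which have other control arrays, with limma's fry, and with camera under a preset and an estimated correlation. That test was likewise added after the files were seen, as were all fits without 5 arrays.

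Those 5 arrays were singled out because their column in the value table and their scanner file ranked the probes differently, with a Spearman correlation under 0.99 (0.871 to 0.982, against 0.9996 to 0.9997 for the other 22), a limit set after seeing the values. Arrays lay on 4 slides, numbered here 1 to 4. Slide was fitted as a fixed and as a random block. The comparisons of doses were repeated with normexp background correction (offset 50), quantile normalization, no filter on dim probes, a filter on all 27 arrays, only the groups of the same sources, a trended and robust spread, array weights (estimated with REML, which did not converge, and gene by gene, which was added after the REML counts had been seen), the authors' values, a minimum fold of 1.5, the replicate number as a block where that could be fitted, and each array left out. Normexp was run on the median signal, because the files used here held no mean signal. Overlaps between doses of a source, which share control arrays, were set beside 20 simulations of unchanged groups for correlations and covariances and 10 for shared calls. In them each probe had the same spread on all arrays. Without the 5 arrays these simulations kept the group sizes that remained, and probes for the steps between doses were also chosen in a mean weighted by arrays. Within a slide, direction was checked on the 100 probes with the smallest p in a fit without the slide's arrays of both groups. These additions were chosen after the data were seen.

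Scripts were tested on simulated data before use. With the spread of these arrays and 200 of 14738 probes changed in the comparison of pure 2.5 ppm with its control, 38.0% of probes changed 2-fold, 69.5% of those changed 4-fold and 79.5% of those changed 8-fold were called, with 5, 10 and 12 false calls. In a simulated comparison of fresh 5 ppm with its control, 13 of 200 sets of unchanged probes had a fry p below 0.05. In these simulations probes varied independently of each other, each with the same spread on all arrays. The rising set of pure 2.5 ppm had an estimated correlation of 0.137 between its probes, so that share does not carry over to it. The number of arrays limits the precision: the median standard error of a dose effect was 0.33 on the log2 scale. Each SE below comes from the spread pooled over all 9 groups, and n is the number of arrays per group. For 1 probe it is therefore the same in every dose comparison, whatever the spread in the groups compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.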

Results

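The series asked how fathead minnow embryos respond, up to hatching, to increasing doses of 3 sources of naphthenic acids. Expression was measured in 27 samples of newly hatched larvae: 3 each of a salt control, a lower and a higher dose for fresh process water, aged process water and pure naphthenic acids. The dose ranges differed between sources and shared only 10 ppm, given as fresh and as aged. The 75th percentile of the processed signal ranged from 582 to 2044 between arrays, and every array had at least 10930 probes well above background. The exposure to 2.5 ppm of pure naphthenic acids had the most called probes, 239, of which 207 rose. At an unadjusted p below 0.05 it had 1734 probes, fewer than fresh 10 ppm (2286) and aged 10 ppm (3595). For fresh 10 ppm that order turned without 5 arrays that stood apart, described below, with 2337 against 3039 at pure 2.5 ppm. Only 1 aged salt array then remains, so aged 10 ppm is not set beside them. With all arrays the median of all probes was 0.27 at fresh 10 ppm and −0.31 at aged 10 ppm, comparisons that held some of the 5. Array weights called 4421 probes at aged 10 ppm, 3801 of them falls, against 1709 at pure 2.5 ppm. The highest weight, 5.11, went to aged salt replicate 7, a control array that stood apart, with its dimmest probes raised by 1.78 log2 units. The weighted count at aged 10 ppm therefore does not by itself show a larger response than at pure 2.5 ppm.

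A group of 5 arrays stood apart from the others, and each comparison below is also given without them. They were 1 fresh 10 ppm array (replicate 1), 2 aged salt arrays (replicates 7 and 9) and 2 aged 20 ppm arrays (replicates 4 and 6). On them the dimmest 10% of probes lay 4.48, 1.78, 4.83, 1.07 and 2.97 log2 units, in that order, above the mean of the other 22 arrays, while the brightest 10% lay between −0.62 and 0.01 from it. The first principal component, on which the 5 arrays had the 5 highest scores, held 68.7% of the variance. Pure naphthenic acid groups and their control held none of the 5 arrays. Only 1 aged salt array and 1 aged 20 ppm array remain without them, which are then assumed to vary like the other groups.

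**Figure D1:**
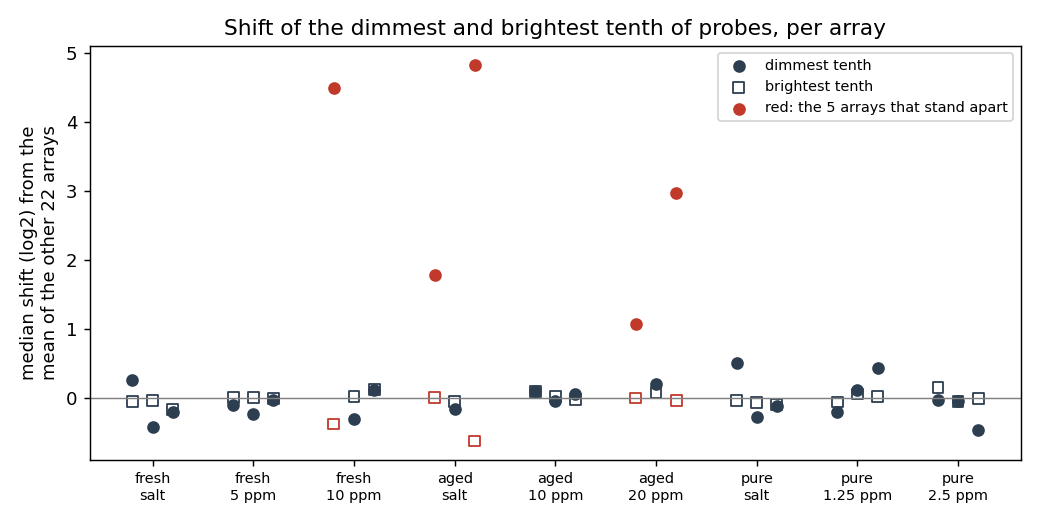
Median shift (log2) of the dimmest 10% of tested probes (filled circles) and the brightest 10% (open squares) from the mean of the 22 other arrays, for each array by group. The 5 arrays in red have dim probes raised by 1.07 to 4.83 log2 units, and on the other arrays the dim probes stay below all of these.

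Pure naphthenic acids at 2.5 ppm raised 207 probes and lowered 32 of the 14738 tested against the pure salt control (3 arrays each). The rises had a median of 1.33 on the log2 scale, from 0.56 to 5.93, and 42 of them were at least 4-fold. The falls were smaller, with a median of −0.95 and a largest fall of −1.90. The largest rise was that of probe UF_Ppr_AF_106707, by 5.93 ± 0.87 (SE, n = 3; limma adjusted p = 4.00e-04), from −5.44 ± 0.06 (SD, n = 3) in the control to 0.48 ± 0.50 (SD, n = 3), on the log2 scale relative to the 75th percentile. The SE of UF_Ppr_AF_106707 pools the spread over all groups, and its SD in aged salt was 2.13. Probe UF_Ppr_AF_111904 rose by 5.82 ± 0.47 (SE, n = 3; limma adjusted p = 5.39e-07). The largest falls were those of UF_Ppr_AF_111977, by −1.90 ± 0.46 (SE, n = 3; limma adjusted p = 0.0379), and UF_Ppr_AF_111117, by −1.83 ± 0.42 (SE, n = 3; limma adjusted p = 0.0281). Both falling probes were well above background on 1 of the 3 exposed arrays, both lost their call under quantile normalization, and with normexp both turned to rises of 0.45 and 0.63 that did not pass. UF_Ppr_AF_111977 also missed the threshold without the 5 arrays (limma adjusted p = 0.0501). With the 5 arrays left out, which are in neither group and enter through the shared spread, 301 probes rose and 174 fell, among them all 207 rises and 29 of the 32 falls. The share of rises among called probes was 86.6%, against 97.3% (144 rises, 4 falls) under quantile normalization, 100% (63 rises, 0 falls) with normexp and 63.4% without the 5 arrays. Falls outnumbered rises without the 5 arrays with slide as a block (335 rises, 372 falls) and with array weights (677 rises, 1032 falls). The median of all probes was −0.12, and −0.03 under quantile normalization. Leaving out pure 2.5 ppm replicate 4 left 124 called probes and leaving out pure salt replicate 8 left 139, with 1 fall each, while leaving out pure 2.5 ppm replicate 5 gave 202 rises and 92 falls. With slide as a block 260 probes rose and 80 fell. Slide 3 was the one slide with arrays of both groups (1 exposed, 2 control). Of the 100 probes with the smallest p in a fit without these 3 arrays, 94 had the same direction within the slide, against 58.6% of all probes.

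**Figure D2:**
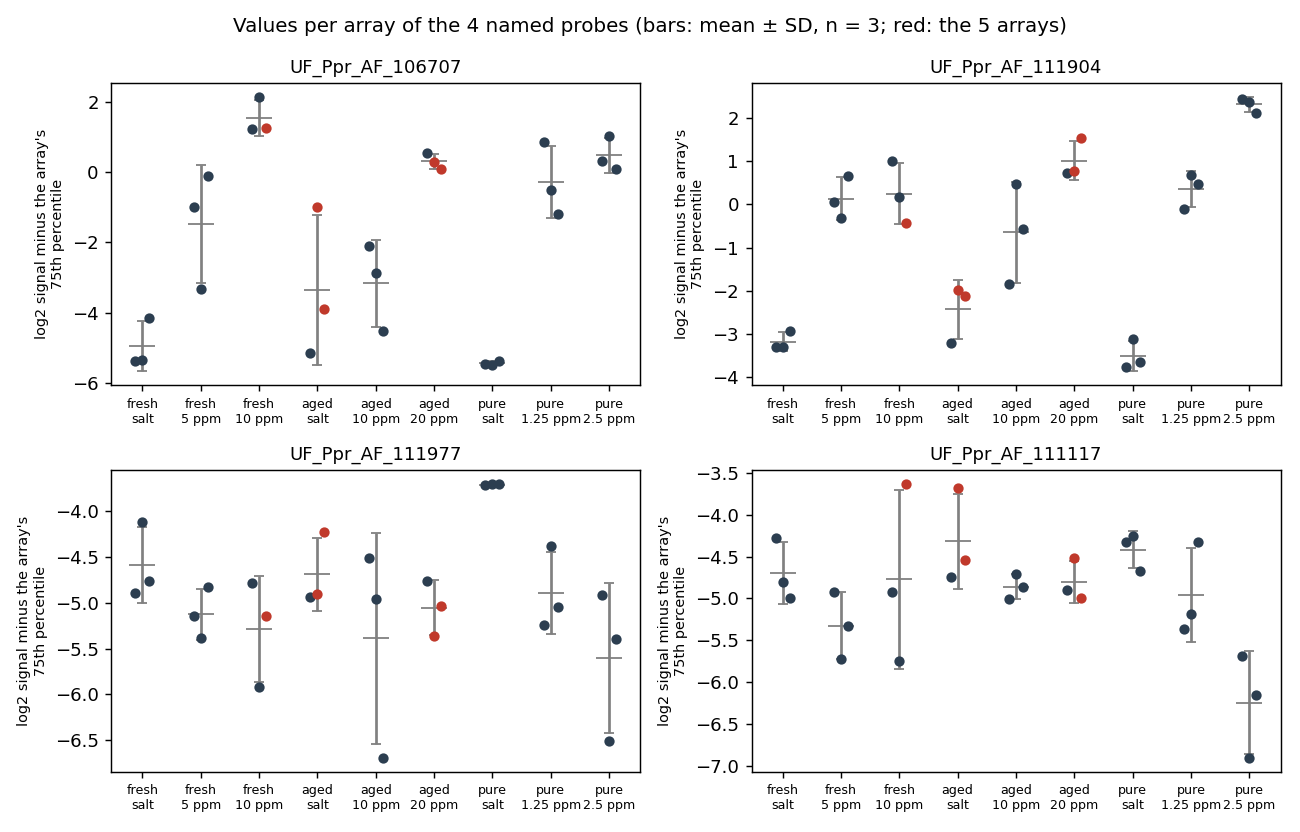
Log2 processed signal minus the 75th percentile of the array for 4 probes in each of the 9 groups; points are arrays (red: the 5 arrays that stand apart) and bars the mean ± SD (n = 3). UF_Ppr_AF_106707 and UF_Ppr_AF_111904 rose by 5.93 and 5.82 at pure 2.5 ppm, while UF_Ppr_AF_111977 and UF_Ppr_AF_111117 changed by −1.90 and −1.83, calls lost under quantile normalization and turned in direction with normexp.

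At 1.25 ppm of pure naphthenic acids 25 probes rose and 0 fell, and all 25 also rose at 2.5 ppm, where independent lists would share 0.351. UF_Ppr_AF_106707 rose by 5.16 ± 0.87 (SE, n = 3; limma adjusted p = 0.0128) and UF_Ppr_AF_111904 by 3.86 ± 0.47 (SE, n = 3; limma adjusted p = 0.00120). The fold changes of both doses correlated at r = 0.65 across probes, which are not independent replicates, against 0.50 in simulated unchanged groups sharing their controls. Their covariance, 0.132, was below the simulated 0.179 but above the 0.0583 simulated without the 5 arrays, and simulated comparisons shared 0 calls on average. With no changed probes hardly any calls can occur in such simulations, so the 0 says little about how much overlap shared controls add. The 3 control arrays were not split between the doses, so part of the overlap may come from them. Leaving out the 5 arrays gave 51 rises and 1 fall, a fit of the pure groups alone 12 calls, normexp 0, and array weights 413 rises and 341 falls. Leaving out any one of the 6 arrays left between 5 and 14 calls, the fewest without pure salt replicate 8. Within slide 2 (1 array of each group) 84 of 100 probes chosen in the same way without these arrays kept their direction (55.7% of all probes).

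The step from 1.25 to 2.5 ppm raised 2 probes and lowered 0, with 518 at an unadjusted p below 0.05, and 11 probes were called without the 5 arrays and 91 (55 rises, 36 falls) with array weights. Of the 164 probes that rose in the mean of both doses against the control, a choice that does not depend on which dose was higher, 158 were higher at 2.5 ppm than at 1.25 ppm, by a median of 0.56 (fry adjusted p over 3 sources = 6.25e-06 in limma), while the median of all probes was −0.07. All 9 probes that fell in that mean were lower at 2.5 ppm. With the 5 arrays left out 225 of 238 rising probes were higher at 2.5 ppm, by a median of 0.48 (fry adjusted p = 7.59e-05). Leaving out pure 1.25 ppm replicate 1 gave 5 called probes for the step, and leaving out pure 1.25 ppm replicate 2 or 3 or pure 2.5 ppm replicate 4 or 6 gave 0.

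Fresh process water at 10 ppm raised 34 probes and lowered 15 against the fresh salt control. The rises had a median of 1.49 on the log2 scale. UF_Ppr_AF_106707 rose by 6.51 ± 0.87 (SE, n = 3; limma adjusted p = 0.00130), its largest change in the series, and UF_Ppr_AF_111904 by 3.42 ± 0.47 (SE, n = 3; limma adjusted p = 0.00149). For 2 of the 34 rising probes no control array was well above background. The median of all probes was 0.27 with this scaling and −0.04 under quantile normalization, so the direction of small changes depends on the scaling, and quantile normalization called 35 rises and 23 falls, while the authors' values gave 42 rises and 6 falls. Without the 5 arrays 27 probes rose and 2 fell, 21 of the rises and 0 of the falls being the same probes. A fit of the fresh groups alone gave 4 rises and 0 falls, normexp 2 rises and 0 falls, and array weights 76 rises and 23 falls. Leaving out any one of the 6 arrays moved the count by over 1.5 times: without fresh 10 ppm replicate 2 it was 288 (120 rises, 168 falls), and without any other of the 6 it was between 12 (fresh salt replicate 9) and 25 (fresh salt replicate 7), with 20 without replicate 1 of the exposed arrays. Within slide 2 (1 exposed and 2 control arrays) 74 of 100 probes chosen without these arrays kept their direction (52.6% of all probes).

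At 5 ppm of fresh process water 11 probes rose, by a median of 1.17, and 0 fell. UF_Ppr_AF_111904 was among them (3.31 ± 0.47, SE, n = 3; limma adjusted p = 0.0124), and UF_Ppr_AF_106707 was not, at 3.48 ± 0.87 (SE, n = 3; limma adjusted p = 0.253). Of the 11 rises 10 were also called at 10 ppm, against 0.0254 for independent lists, and the fold changes of both doses correlated at r = 0.41 across probes (0.50 in simulated unchanged groups sharing their controls, covariance 0.140 against 0.178). Leaving out the 5 arrays gave 24 rises and 4 falls, and a correlation of 0.73 (0.45 in simulated unchanged groups of the remaining sizes, covariance 0.168 against 0.0580). Leaving out any one of the 6 arrays left between 0 and 2 calls, normexp and a fit of the fresh groups alone gave 0, slide as a block gave 18, and array weights gave 134 rises and 70 falls. Within slide 3 (1 array of each group) 92 of 100 probes chosen without these arrays kept their direction (64.2% of all probes). No probe was called between 5 and 10 ppm by limma (860 at an unadjusted p below 0.05, and 0 under quantile normalization). Of the 43 probes that rose in the mean of both doses 31 were higher at 10 ppm, by a median of 0.28 (fry adjusted p = 0.0696), while the median of all probes was 0.25 higher, and −0.04 under quantile normalization. Leaving out the 5 arrays left the higher dose with 2 arrays, so the rising probes were chosen in a mean weighted by arrays. Of 63 such probes 54 were higher at 10 ppm, by a median of 0.21 (fry adjusted p = 0.0525), while the median of all probes was 0.05 higher. Chosen in the plain mean, which favours the dose with fewer arrays, 62 of 71 were higher (fry adjusted p = 0.0405).

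Aged process water at 20 ppm raised 40 probes and lowered 1 (by −6.48) against the aged salt control, and at 10 ppm it raised 17 and lowered 2. Normexp called 0 probes at either dose, and a fit of the aged groups alone called 0 at 10 ppm and 1 fall at 20 ppm. Quantile normalization gave 11 rises and 0 falls at 10 ppm, and the authors' values gave 27 rises and 4 falls at 20 ppm. The rises had medians of 1.19 and 1.35, and 14 probes rose at both doses, against 0.0461 for independent lists. UF_Ppr_AF_111904 rose at 20 ppm by 3.44 ± 0.47 (SE, n = 3; limma adjusted p = 9.89e-04), a call lost without the 5 arrays (3.94, limma adjusted p = 0.0872), and was at 1.78 ± 0.47 at 10 ppm (SE, n = 3; limma adjusted p = 0.172). UF_Ppr_AF_106707 was at 3.66 ± 0.87 and 0.19 ± 0.87, and at 5.69 and 1.99 without the 5 arrays, none of them past the threshold. UF_Ppr_AF_111904 was then at 2.56 at 10 ppm, also not past it. The aged groups held 4 of the 5 arrays. With all 5 left out 6 probes rose and 3 fell at 20 ppm and 8 rose and 14 fell at 10 ppm, and 3 of the 40 and 3 of the 17 rises were called again. All 40 and all 17 still had fold changes above 0, with medians of 1.07 and 1.19. These probes had been chosen as rises with the remaining arrays included, so the choice favoured that direction and it is no separate support. The median standard error at 20 ppm rose from 0.33 to 0.42, with 1 array left in each group compared. Leaving out aged salt replicate 8, the control array that did not stand apart, gave 4505 calls at 10 ppm (581 rises, 3924 falls), and array weights gave 620 rises and 3801 falls there, while leaving out aged salt replicate 9 gave 6, replicate 7 gave 42 and aged 10 ppm replicate 3 gave 1. At 20 ppm the count fell to 18, 22, 25 and 27 without aged 20 ppm replicate 4, aged 20 ppm replicate 6, aged salt replicate 9 and aged 20 ppm replicate 5. Array weights gave 123 rises and 248 falls at 20 ppm. Slide as a block gave 38 calls at 10 ppm and 42 at 20 ppm. Of 100 probes chosen without the arrays of a slide, 88 and 84 kept their direction at 10 ppm within slides 2 and 4 (72.6% and 70.2% of all probes), and 81 and 78 at 20 ppm within slides 3 and 4 (42.0% and 37.6%). Each slide held 1 array of each group, 1 of which stood apart. The fold changes of both doses correlated at r = 0.78 across probes (0.50 in simulated unchanged groups sharing their controls, covariance 0.394 against 0.177), and at 0.63 without the 5 arrays (0.61 in simulated unchanged groups of the remaining sizes, covariance 0.209 against 0.174). The simulated arrays all had the same spread, while 2 of the shared aged salt arrays stood apart. The simulated 0.50 and 0.177 may therefore be too low for this source.

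No probe was called between 10 and 20 ppm of aged process water by limma (351 at an unadjusted p below 0.05, 0 under quantile normalization), and 4 were called without the 5 arrays. Of the 59 probes that rose in the mean of both doses 40 were higher at 20 ppm, by a median of 0.13 (fry adjusted p = 0.283), while the median of all probes was 0.18 higher, and −0.01 under quantile normalization. Of the 11 probes that rose in the mean weighted by arrays without the 5 arrays, 7 were higher at 20 ppm, by a median of 0.32 (fry adjusted p = 0.00112), while the median of all probes was 0.11 higher. That value rests on 1 array at 20 ppm and 1 control array. Chosen in the plain mean, 8 of 11 were higher (fry adjusted p = 1.74e-04).

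**Figure D3:**
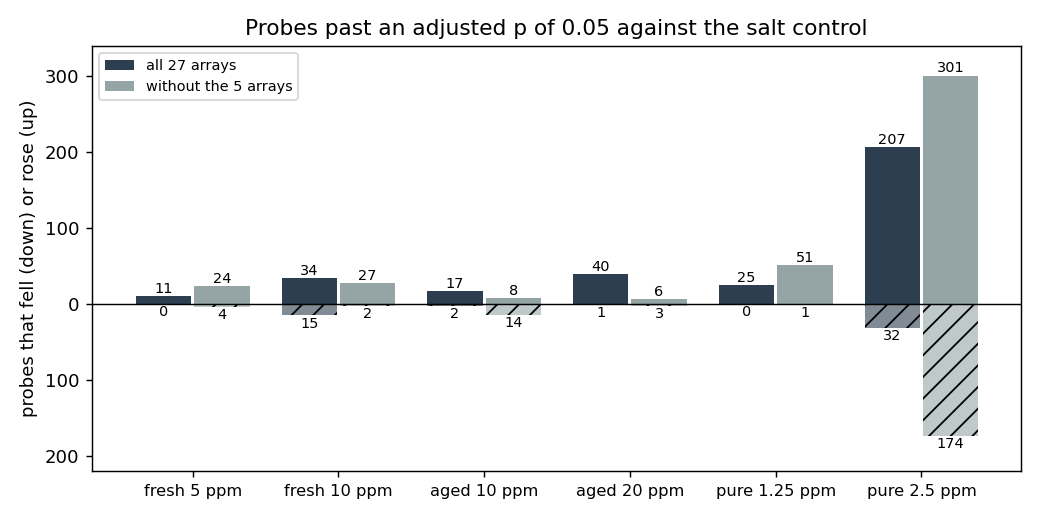
Number of probes past a limma adjusted p of 0.05 in each dose against the salt control of its source, rises above 0 and falls (hatched) below it, with all 27 arrays (dark) and without the 5 arrays that stand apart (light). Pure 2.5 ppm has the most calls in both, 207 rises and 32 falls against 301 and 174.

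The sources were then compared through their calls and fold changes, which share no control arrays. They do share the spread of each probe, estimated over all 27 arrays, so calls are not independent and the overlap of independent lists is only a rough guide. Of the 34 probes that rose at fresh 10 ppm 30 also rose at pure 2.5 ppm (0.478 for independent lists), and so did 37 of the 40 that rose at aged 20 ppm (0.562 for independent lists). A group of 18 probes rose in at least 1 dose of every source, with medians between 1.14 (fresh 5 ppm) and 2.53 (pure 2.5 ppm). By limma 0 probes were called in opposite directions in any pair of dose comparisons of different sources. With at most 32 falls in a dose comparison (pure 2.5 ppm), few such calls could occur, so this count says little about agreement. Without the 5 arrays 5 probes rose in every source, 2 of them among the 18, and 27 of 27 rises at fresh 10 ppm, 23 of 24 at fresh 5 ppm, 5 of 8 at aged 10 ppm and 5 of 6 at aged 20 ppm were shared with pure 2.5 ppm.

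As a set, the 207 probes that rose at pure 2.5 ppm were higher in all 4 fresh and aged exposures. Their median fold change was 0.49 at fresh 5 ppm (193 of 207 above 0), 0.61 at fresh 10 ppm (196), 0.60 at aged 10 ppm (195) and 0.61 at aged 20 ppm (192), while the medians of all probes were −0.03, 0.27, −0.31 and −0.15. The largest fry adjusted p of these 4 over a family of 10 tests was 1.71e-05 in limma, and with camera's estimated correlation the largest adjusted p was 0.00274. The 32 falling probes had medians of −0.39, −0.46, −0.37 and −0.27 in the same order, with fry adjusted p of 0.0166, 0.00430, 0.0166 and 0.107. Their adjusted p with an estimated correlation was 0.0555, 0.0168, 0.275 and 0.275. The 174 falling probes of the fit without the 5 arrays had medians of −0.27, −0.29, −0.24 and −0.09, with fry adjusted p of 0.0290, 0.0305, 0.344 and 0.627, and the lowest adjusted p with an estimated correlation was 0.127. The 301 rising probes of that fit had medians of 0.42, 0.58, 0.52 and 0.48, with a largest fry adjusted p of 0.00611 and a largest adjusted p with an estimated correlation of 0.0625 (aged 20 ppm). With slide as a block the medians of the 260 rising probes were 0.61, 0.68, 0.61 and 0.64.

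**Figure D4:**
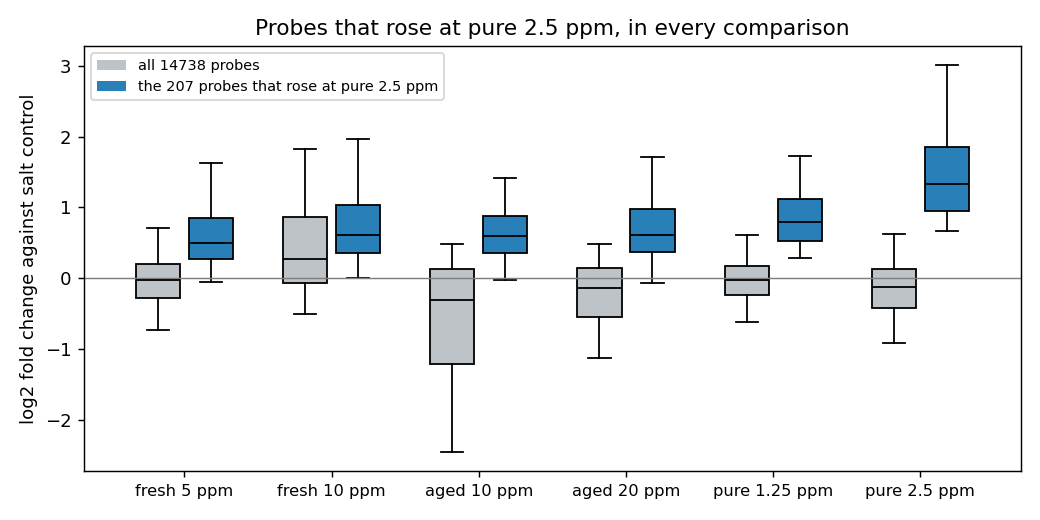
Log2 fold change against the salt control of the same source for all 14738 probes (grey) and the 207 probes that rose at pure 2.5 ppm (blue); boxes show the quartiles and median, whiskers the central 90% of probes. The blue medians are 0.49, 0.61, 0.60 and 0.61 in the fresh and aged comparisons.

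Across all probes the correlation of fold changes between sources depended on the 5 arrays. For the mean of both doses r was −0.29 between fresh and aged, 0.32 between fresh and pure and 0.32 between aged and pure, across probes that are not independent replicates. They were 0.27, 0.47 and 0.21 without the 5 arrays, and without fresh 10 ppm replicate 1 alone the value for fresh and aged was 0.25. With slide as a block they were 0.12, 0.41 and 0.69.

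At 10 ppm, the one dose given from both process waters, the effect of fresh minus that of aged passed the threshold for 0 probes in limma, with 4586 at an unadjusted p below 0.05, and for 0 under quantile normalization. The difference was 6.32 ± 1.23 (SE, n = 3; limma adjusted p = 0.138) for UF_Ppr_AF_106707 and 1.64 ± 0.66 (SE, n = 3; limma adjusted p = 0.138) for UF_Ppr_AF_111904. The rising set of pure 2.5 ppm differed by a median of −0.01 (fry adjusted p = 0.830), while the median of all probes was 0.47, and −0.13 under quantile normalization. These values do not show that both waters acted alike. Without the 5 arrays 5 probes were called, 3 with a higher fresh effect and 2 with a higher aged effect, and 409 had an unadjusted p below 0.05, in a fit with 1 aged salt array. UF_Ppr_AF_106707 was then at 4.66 and UF_Ppr_AF_111904 at 1.20. Leaving out aged salt replicate 8 gave 4893 calls (4592 with a higher fresh effect), leaving out aged salt replicate 7 gave 1, and array weights gave 987 (934 with a higher fresh effect). Without replicate 8 the aged control was replicates 7 and 9, whose dimmest probes were raised by 1.78 and 4.83 log2 units. The highest weight, 5.11, also went to replicate 7. Raised control probes would by themselves give a higher fresh effect, so the counts of 4893 and 987 do not by themselves show a difference between the waters.

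The 3 salt controls, which limit how far effects against different controls can be set side by side, differed at 2 probes by limma's moderated F-test and at 20 without the 5 arrays. With slide as a block the count was 0, with array weights 5512 and without aged salt replicate 8 it was 1657, while leaving out aged salt replicate 7 gave 8, pure salt replicate 7 gave 1, and any fresh salt array or pure salt replicate 8 gave 0.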

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

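The tests of the 5 arrays, of the share of rises and of the difference at 10 ppm without the 5 arrays were chosen after the result was seen, as were the set of rising probes itself and the test that followed the same 207 probes. No test of single outlying arrays was run, and groups of 3 arrays would give it little precision.

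A difference between fresh and aged effects at 10 ppm was found for 5 probes once the 5 arrays were left out, which left 1 aged salt array, by the test of the difference itself, and for 0 in limma with all 27 arrays, where 4586 had an unadjusted p below 0.05. The count was 4893 without aged salt replicate 8 and 987 with array weights.

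The 5 arrays with raised dim probes lay on 4 slides beside arrays that did not stand apart, which argues against a difference between slides as the cause. They came from 3 groups, 1 of them a salt control, and in 0 of those groups did all 3 arrays stand apart, which argues against the exposure as the cause. Control probes whose names begin with ETG exceeded the negative control probes by at least 2.34 signal units on each of the 5 arrays and by at most 1.06 on the other 22. For aged 20 ppm replicate 4 this holds for the difference only. Its medians were 8.89 (ETG) and 6.56 (negative), which as a ratio is not above pure 1.25 ppm replicate 3 (3.89 and 2.84), an array that did not stand apart. A candidate explanation, weakest for aged 20 ppm replicate 4, is therefore signal on dim probes that does not come from a matching transcript. The 5 arrays are also the last samples of the series, listed out of the slide order that the other 22 follow. The file headers hold a scan date for each array, which was not compared here. Whether the 5 arrays were processed separately was not tested. What raised the signal stays open, as do the RNA and the hybridisation of these samples.

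The rise of the pure 2.5 ppm set in fresh and aged exposures was set against the placing of arrays, since 8 of 9 salt control arrays lay on slides 2 and 3 and 12 of 18 exposed arrays on slides 1 and 4. For the same 207 probes, the lowest ratio of the median with slide as a block to that without it, over the 4 comparisons, was 1.004, and the lowest without the 5 arrays was 0.843. With the set chosen anew in each fit (260 and 301 probes) they were 1.02 and 0.790. These values argue against the slides and the 5 arrays as the whole cause. A response common to the 3 sources may explain it, as a hypothesis found and tested on the same arrays. Differences in hatching time or handling between exposed and control larvae were not tested.

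More probes rose than fell at pure 2.5 ppm, 86.6% of those called. Under quantile normalization the share was 97.3%, which argues against the scaling to the 75th percentile as the cause. Without the 5 arrays it was 63.4%, so the spread these arrays add to dim probes may hide falls. Falls outnumbered rises without the 5 arrays with slide as a block (335 rises, 372 falls) and with array weights (677 rises, 1032 falls), so an excess of rises stays open.

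Splits of the same arrays tested how often other groupings give as many calls. Arrays were exchanged across slides, on which controls and exposed arrays were unevenly placed, so these splits do not set placing aside. For the mean of both doses, of 84 splits, 1 gave as many calls as the real split for fresh (56, highest other 4). For pure it was 1 too (173, highest other 133). In both this was the real split itself, a share under 0.05 that was not adjusted over sources. For aged 3 splits, the real one among them, gave as many (64, highest other 5682). The split with 5682 calls set aged salt replicates 7 and 9 and aged 20 ppm replicate 6 against the rest, which points to a structure of the samples. These arrays are all among those that stand apart, so the aged splits do not exclude chance. The highest other pure split set the 2.5 ppm arrays apart. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Their real count and highest other were 11 and 0 (fresh 5 ppm), 49 and 0 (fresh 10 ppm), 19 and 0 (aged 10 ppm), 41 and 3413 (aged 20 ppm), 25 and 0 (pure 1.25 ppm) and 239 and 1 (pure 2.5 ppm). Only the real split itself reached the real count, except for aged 20 ppm, where 2 splits did with the real one included. For the step between pure doses they were 2 and 2 (2 splits as large, the real one included). Chance could not be excluded for the salt controls (2, highest other 16, 7 of 100 with the real split included). The real count was 0 for the fresh and aged steps (highest other 0 in 10 splits each) and for fresh minus aged at 10 ppm (highest other 514 in 100 drawn splits), so every split was as large whatever the data, which says nothing about chance.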

How the results depend on the processing

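The fits without the 5 arrays, every alternative for the set of rising probes, most of those for correlations between sources and 2 for the named probes were chosen after the data were seen. Counts of called probes are listed in a fixed order: fresh 5 and 10 ppm, aged 10 and 20 ppm, pure 1.25 and 2.5 ppm, the mean of both doses for fresh, aged and pure, the step between doses for fresh, aged and pure, fresh minus aged at 10 ppm, and the salt controls. They were 11, 49, 19, 41, 25, 239, 56, 64, 173, 0, 0, 2, 0 and 2 as reported. The cause of a change was not tested except where stated.

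Normexp on the median signal gave 0, 2, 0, 0, 0, 63, 6, 0, 49, 0, 0, 0, 0 and 0. Quantile normalization gave 14, 58, 11, 33, 14, 148, 39, 68, 121, 0, 0, 2, 0 and 0. Testing only probes well above background on all 27 arrays, which tests fewer probes, gave 19, 128, 32, 54, 39, 333, 122, 100, 237, 0, 0, 11, 0 and 3. Slide as a fixed block gave 18, 67, 38, 42, 28, 340, 87, 136, 233, 0, 0, 1, 0 and 0. Fits of only the groups of the same sources, which have fewer arrays, gave 0, 4, 0, 1, 12, 189, 0, 0, 124, 0, 1, 0, 0 and 0. A trended and robust spread gave 22, 120, 42, 59, 44, 297, 122, 108, 230, 0, 1, 10, 0 and 6. The authors' values gave 21, 48, 12, 31, 27, 184, 60, 32, 135, 0, 0, 7, 0 and 1. Leaving out the 5 arrays gave 28, 29, 22, 9, 52, 475, 90, 21, 299, 0, 4, 11, 5 and 20. The same with slide as a block gave 16, 25, 19, 4, 21, 707, 151, 12, 412, 0, 2, 7, 4 and 14. The authors' values without the 5 arrays gave 48, 50, 63, 48, 60, 489, 221, 61, 405, 1, 24, 24, 28 and 62. Array weights gave 204, 99, 4421, 371, 754, 1709, 403, 3654, 1893, 0, 0, 91, 987 and 5512, with weights from 0.0782 (fresh 10 ppm replicate 1) to 5.11 (aged salt replicate 7). They were estimated gene by gene, a method added after the counts from REML weights, the default, had been seen. REML did not converge, gave aged salt replicate 7 a weight of 227, and called 306 probes at fresh 5 ppm, 84 rises and 23 falls at fresh 10 ppm, and then 7127, 3102, 2011, 3228, 464, 7670, 3595, 0, 0, 293, 2672 and 10334. At pure 2.5 ppm these were 1050 rises and 2178 falls. No filter on dim probes, slide as a random block and a minimum fold of 1.5 left every count within 1.5 times.

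Leaving out each array of the compared groups in turn gave, in the same order, 0 to 2, 12 to 288, 1 to 4505, 18 to 42, 5 to 14, 124 to 294, 13 to 116, 20 to 2376, 94 to 190, 0 to 1, 0 to 0, 0 to 5, 0 to 4893 and 0 to 1657 called probes.

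The correlations of fold changes for fresh and aged, fresh and pure, and aged and pure were −0.295, 0.323 and 0.323. They were −0.165, 0.189 and 0.329 with normexp, −0.281, 0.404 and 0.202 under quantile normalization, 0.0298, 0.481 and 0.495 for probes above background on all arrays, 0.124, 0.409 and 0.692 with slide as a fixed block, −0.252, 0.309 and 0.387 with slide as a random block, 0.15, 0.394 and 0.164 with array weights, 0.0357, 0.421 and 0.295 for the authors' values. Without the 5 arrays they were 0.274, 0.472 and 0.211, with slide as a block too 0.497, 0.606 and 0.453, and for the authors' values 0.334, 0.491 and 0.312. With each array left out they ranged from −0.485 to 0.249, 0.174 to 0.472, 0.180 to 0.372, and the value for fresh and aged turned positive without fresh 10 ppm replicate 1 (0.249) or aged salt replicate 9 (0.187).

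By fry, the set of probes that rose at pure 2.5 ppm, chosen anew in each fit, kept its direction and its side of the threshold in the 4 fresh and aged comparisons under every alternative run for it, with medians from 0.46 to 0.72 on the log2 scale when arrays were left out in turn. The lowest medians came from the authors' values without the 5 arrays: 0.370 and 0.460 at fresh 5 and 10 ppm, and 0.400 and 0.369 at aged 10 and 20 ppm. With an estimated correlation the call at aged 20 ppm was lost without the 5 arrays (adjusted p = 0.0625). At pure 2.5 ppm, UF_Ppr_AF_106707 and UF_Ppr_AF_111904 kept their calls in all 18 alternatives, and UF_Ppr_AF_111977 and UF_Ppr_AF_111117 kept their direction but lost their calls in 10 and 8, and turned to 0.45 and 0.63 with normexp.

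No paired analysis was possible for most comparisons because the compared groups share no replicate number. With the replicate number as a block, fresh minus aged at 10 ppm gave 0 calls and the salt controls 0. Of the 27 pairs of arrays with the same number 11 had deviations that correlated above 0.1 (−0.23 to 0.38), and 4 of 27 arrays were closest to one of their own number. These values show no clear pairing across sources and do not exclude it. Each number occurs once in a source, so a pairing of doses within a source was not checked. Signal over background limits the dim probes, of which 470 were not tested.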

Other observations

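The values below were chosen after the data had been seen. Each of the 5 arrays that stand apart had a value-table column that followed its own scanner file less closely than the other arrays did. Over the 2281 brightest probes, deviations from the mean of the other 22 arrays in those columns correlated at 0.731 to 0.887 with their own scanner file and at most at 0.632 with another, so all 5 columns matched their own file best, as did all 22 others. How the authors made those values is not given in the sources used here.

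Non-uniform spots numbered 518 on fresh 10 ppm replicate 1, 346 on aged salt replicate 7, 238 on aged salt replicate 9, 82 on aged 20 ppm replicate 6 and 0 on aged 20 ppm replicate 4, against at most 22 on the other arrays.

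Some probes share a contig name with a partner probe whose name ends in ms. For 93 such pairs with both probes well above background on all arrays, the fold changes of the mean of both doses, without the 5 arrays, correlated at 0.616 for pure, 0.218 for aged and 0.131 for fresh.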
